A study of Homo sapiens with 12 samples.

How the data were processed

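RNA from both channels of alveolar lung chips was measured on the nCounter platform, which counts barcoded probes hybridised to RNA without amplification. The vascular channel held HuLEC-5a, an established line of human lung microvascular endothelial cells. The other channel held primary human epithelial cells. Per the labels, the probe set was a human organ transplant panel with added custom probes, RNA was extracted with a column kit from each channel of each chip, and nCounter and nSolver were used. Control probes, background steps, flow cells and lanes are not given in the sources used here. The labels describe static cold storage of the chips for 6 h with a perfused organ preservation solution, and a 24 h step abbreviated IRI. They do not say whether the cold storage samples of the table passed through the 24 h step, so the contrast is named by its cold storage label alone.

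The deposited values are counts per probe, whole numbers of at least 1 with no gaps among the low values, for 780 targets in 12 samples. No normalisation is visible in them: the totals per sample and the housekeeping genes differ between samples. A count of 0 may have been raised to 1 before deposition. The 4 viral targets (BK virus large T and VP1, cytomegalovirus UL83 and Epstein-Barr virus LMP2) were left out of all fits and used as a gauge of background. Of the 776 human targets, 760 carried a current gene symbol, 3 matched only as a synonym and 13 were combined, isoform or receptor subgroup probes kept under the names in the table. Total counts ran from 418043 to 751623 in endothelial samples and from 1010540 to 1164547 in epithelial samples. Counts from the 3 samples of each group differed by more than counting noise in every pair, so no sample was counted as a duplicate.

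Samples were grouped by channel and condition from their labels, with 3 samples in each of 4 groups. Nothing in the labels says that the samples of a group were separate cultures or whether same-numbered samples of the 2 channels shared a chip. The p-values therefore measure the spread between these samples, which may be technical. Same-numbered samples were not treated as pairs in any main test.

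Genes with at least 20 counts in at least 3 of the 12 samples were tested, which kept 580. Counts were scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, 2-sided) as 4 group means over all 12 samples, with 8 residual degrees of freedom. Contrasts were cold storage over normal in each channel, the difference of those effects (endothelial less epithelial), and endothelial over epithelial in normal chips. Benjamini-Hochberg adjusted p-values under 0.05 were called. Normalised counts are deposited counts divided by the TMM-scaled library size and brought to the geometric mean library, and values after ± are SDs unless SE is written. Adjusted p-values in the text are from edgeR unless another tool is named.

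Before the data were examined, 18 gene lists, 4 lists of cell type markers, the contrasts, the filter and the rule for named genes were fixed. The 15 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The 3 smaller lists (heat shock, cold shock and unfolded protein response, cell cycle, autophagy and lysosome) were only counted. In each cold storage comparison the named genes were the 6 largest rises and 6 largest falls among called genes whose groups did not overlap and whose higher group averaged at least 50 normalised counts. Added to these were the 2 members with the smallest p of each list with at least 3 tested members. For the difference between channels the first part alone applied, and for the comparison of channels the first part and the 4 largest differences of each marker list. Genes named outside this rule are marked as chosen after their values were seen.

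The fits were tested on simulated data: counts for 580 genes drawn from the fitted means and dispersions, with 50 genes changed at each of 4 folds. In the endothelial contrast 56% of the genes changed 1.25-fold and 92% of those changed 2-fold were called, with 7 of 162 calls false. In the epithelial contrast the same shares were 48% and 98%, with 11 of 176 calls false. A simulated 1.25-fold fall of the interferon list was called by camera (adjusted p = 3.88e-27) with no other list, and with no change simulated 0 of 15 lists were called. The simulated genes varied independently, while the correlation estimated within the interferon list was 0.416, so the simulation does not test the preset correlation of 0.01.

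Alternatives were scaling by 17 housekeeping genes, deposited counts without scaling, median-of-ratios scaling, quantile normalisation, limma on log2 values with a pseudocount of 10 or with values under 20 set to 20, and no filter or a filter at 50 counts. Further ones were no abundance trend, array weights, DESeq2 1.42.0, fits to the 6 samples compared, the replicate number as a block, and leaving out each sample. Thinning of the endothelial samples to the lowest endothelial total, subtraction of the viral targets and limma with a pseudocount of 1 were added after seeing the data. R 4.3.3 was used, and the plots were drawn with matplotlib.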

Results

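Expression of 776 human targets was counted in the endothelial and epithelial channels of alveolar lung chips kept as normal controls or put through static cold storage, the condition in which donor organs are held before transplantation. Each of the 4 groups held 3 samples. Changes given below for cold storage may include those of the perfused preservation solution and of the 24 h step, if the samples passed through it. Totals averaged 715022 ± 53669 counts in endothelial normal, 529148 ± 96262 in endothelial cold storage, 1106439 ± 50583 in epithelial normal and 1027173 ± 14492 in epithelial cold storage samples (SD, n = 3 each). The endothelial cold storage mean was 74.0% and the epithelial one 92.8% of its normal group (exact permutation p = 0.1 in each channel, 2-sided, the smallest that 3 against 3 samples can give). The 4 viral targets, the gauge of background, gave 4.08 to 23.3 normalised counts in endothelial and 3.09 to 25.5 in epithelial samples, and values in this range are read as background. In total 580 genes were tested.

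The first question was whether each channel of the normal chips carried the transcripts of its own cell type. Endothelial surface and junction genes were far higher in the vascular channel. ECSCR, an endothelial regulator of migration, had 8424 ± 146.1 against 14.6 ± 4.7 normalised counts (SD, n = 3 per group). ENG, a TGF-beta co-receptor, had 4706 ± 267.6 against 32.7 ± 2.8, and TEK, the angiopoietin receptor, 1465 ± 48.4 against 11.4 ± 2.3. TM4SF18, RHOJ and ADGRL4 were the other 3 of the 6 largest differences in this direction, at log2 7.75, 7.64 and 6.93. In the epithelial channel S100A9, a calcium-binding alarmin, had 23929 ± 1160 against 80.2 ± 43.8, the keratin gene KRT19 14104 ± 253.5 against 72.5 ± 42.5, and cdh1 (E-cadherin) 4708 ± 57.5 against 27.9 ± 7.6 normalised counts. S100A8, LCN2, SLPI and CD24 were also over 100-fold higher there, at log2 -8.08, -7.71, -7.57 and -7.51 for endothelial over epithelial. Where the lower channel lies in the range of the viral targets, as for ECSCR, TM4SF18, RHOJ, TEK, ADGRL4, S100A8, LCN2, SLPI, PDPN and CD14, the fitted fold depends on how background counts are treated. Over the other settings on scaled counts it ran from log2 6.07 to 13.4 for RHOJ, 6.86 to 14.2 for TM4SF18 and -7.64 to -0.82 for CD14.

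Of the 23 endothelial markers tested, 18 were higher in the endothelial channel, CAV1 alone was lower (chosen after its values were seen) and 4 did not pass. Of the 14 epithelial markers tested, 10 were higher in the epithelial channel and 3 did not pass. The 3 were AGER, SCGB1A1 and SFTPC, at 13.8, 12.6 and 14.5 normalised counts in epithelial normal samples, within the range of the viral targets. The 10 included CAV1, which is on both marker lists, and SFTPD, at 23.5 ± 1.9, also within that range (these genes chosen after their values were seen). PDPN, an alveolar type I and lymphatic marker, was higher in the endothelial channel (100.3 ± 8.72 against 6.08 ± 0.772 normalised counts, chosen after its values were seen). The mesenchymal markers ACTA2, RGS5 and PDGFRB were higher in the endothelial channel by log2 1.48 ± 0.12, 1.17 ± 0.09 and 0.85 ± 0.26 (SE, n = 3 per group). Of the leukocyte markers 7 of 30 were tested, of which 3 were higher and 3 lower in the endothelial channel and 1 did not pass. CD68, PTPRC and KLRD1 were higher in the endothelial channel by log2 1.21, 1.26 and 0.94. CD14 was higher in the epithelial channel, at 35.3 ± 2.6 against 2.2 ± 1.1 normalised counts, as were CD79A and CD5, at 47.5 ± 1.7 against 24.9 ± 4.6 and 45.4 ± 15.9 against 27.9 ± 4.4 (the last 2 chosen after their values were seen). PDGFRB, PTPRC and KLRD1 averaged under 30 counts in both channels, with their epithelial means in the range of the viral targets. Altogether 472 of 580 genes differed at adjusted p under 0.05, 248 higher in the endothelial and 224 higher in the epithelial channel, 321 of them by more than 2-fold. PDGFRB and KLRD1 did not pass on unscaled counts (adjusted p up to 0.333 and 0.201), and PDGFRB also not with values under 20 set to 20.

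The second comparison asked what differed between cold storage and normal samples in the endothelium. BCL2L11, which encodes the pro-apoptotic protein BIM, fell from 62.1 ± 8.3 to 28.1 ± 6.7 normalised counts, and GBP4, an interferon-induced GTPase, from 153.5 ± 17.3 to 81.0 ± 22.0 (SD, n = 3 per group). The cold storage level of BCL2L11 lay close to the range of the viral targets. Its fold ran from log2 -1.74 to -0.93 over the other settings on scaled counts. CXCR4, the CXCL12 receptor, fell from 108.1 ± 13.4 to 58.7 ± 5.9, and PLA1A, a phospholipase, from 370.6 ± 37.0 to 202.4 ± 24.3. BST2, the antiviral protein tetherin, fell from 3005 ± 1001 to 1727 ± 219.1, and ABCA1, the cholesterol exporter, from 61.0 ± 10.9 to 36.1 ± 5.2. CRP, an acute-phase pentraxin gene, rose from 204.8 ± 10.5 to 328.7 ± 29.7, and PTX3, another pentraxin, from 13794 ± 750.7 to 19316 ± 913.8. CD44, the hyaluronan receptor, rose from 633 ± 34.3 to 914.7 ± 39.6, and the protease gene ADAMTS1 from 756.8 ± 67.0 to 1051 ± 77.5. IRS1 and IL21R also rose, by log2 0.66 ± 0.22 and 0.63 ± 0.20 (SE), from means of 36.7 and 34.8.

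**Figure D1:**
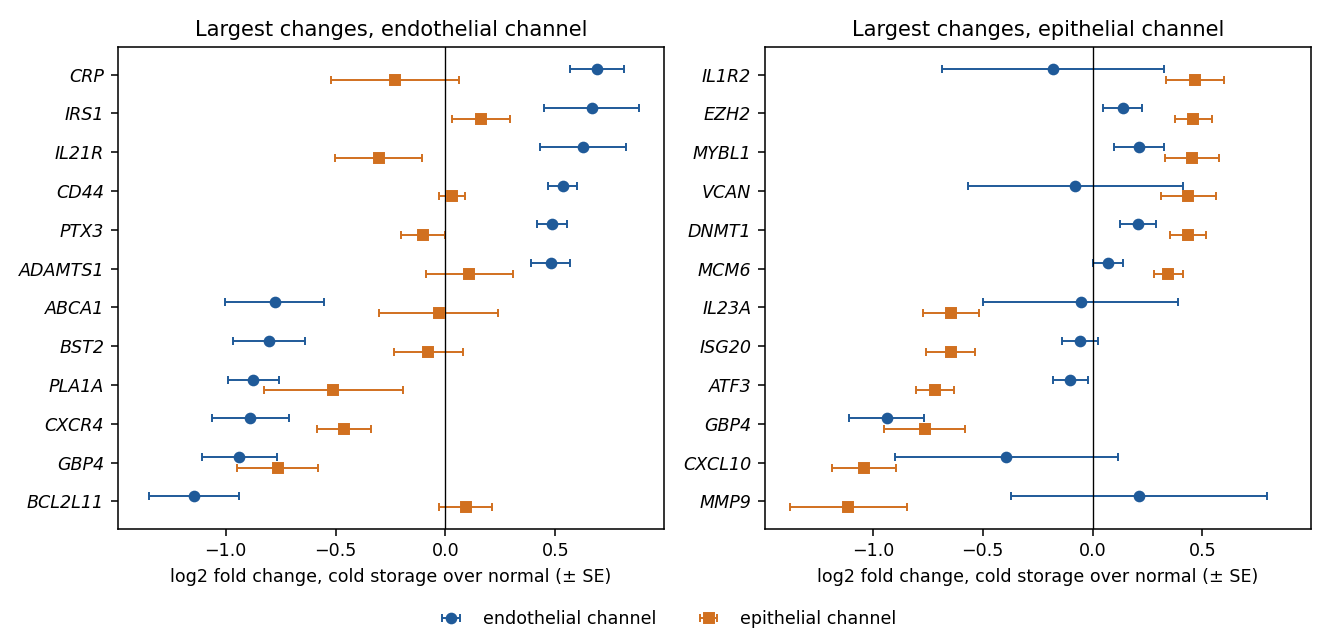
Log2 fold change of cold storage over normal (horizontal axis) for the 6 largest rises and 6 largest falls of the endothelial (left) and epithelial (right) comparisons. They are the largest among called genes whose groups did not overlap and whose higher group averaged at least 50 normalised counts. Circles are the endothelial and squares the epithelial channel, and bars are SEs from fits with 3 samples per group; BCL2L11 lies at -1.15 in the endothelial and GBP4 at -0.94 and -0.76 in the endothelial and epithelial channels.

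Altogether 93 genes changed in the endothelial channel, 32 up and 61 down (adjusted p under 0.05), with a median size of log2 0.42 and 2 genes over 2-fold. Over all 580 tested genes the samples of the groups did not overlap in 161 (27.8%), where chance gives 10%, and 85 of these were called. The direction of the majority depended on the fit: 38 rose and 23 fell after quantile normalisation, and 54 rose and 33 fell when only the 6 endothelial samples were fitted. Without normal replicate 3 and without cold storage replicate 3, 55 and 56 genes were called. BST2 did not pass after quantile normalisation (adjusted p = 0.0515) or with only the 6 endothelial samples (0.058), and PLA1A not after quantile normalisation (0.0836). CRP and ADAMTS1 did not pass under 3 and 4 of 16 other settings, quantile normalisation and limma with a pseudocount of 1 among them (up to 0.151 and 0.711), and CD44 and PTX3 not on unscaled counts (0.568 and 0.7). IRS1, IL21R and ABCA1 lost their calls under 7 of 16, 6 of 15 and 4 of 15 settings (up to 0.383, 0.487 and 0.229). IL21R also lost its call without any endothelial sample other than normal replicate 1 (adjusted p up to 0.194). IRS1 lost it without normal replicates 2 or 3 or cold storage replicates 1 or 2 (up to 0.267), and ABCA1 without normal replicate 3 or cold storage replicates 1 or 3 (up to 0.118).

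Interferon-stimulated genes were the list with the lowest p in the endothelium. Of 37 tested members 15 fell, 0 rose and 22 did not pass (21 fell when adjusted over the list alone). The median log2 fold change was -0.39, with 33 of 37 members negative (camera adjusted p = 8.29e-06, and adjusted p = 0.774 with an estimated correlation). GBP2, a second guanylate-binding protein gene of this list, fell from 134.4 ± 8.9 to 82.1 ± 6.4 normalised counts (SD, n = 3 per group), beside GBP4 and BST2, though not after quantile normalisation (adjusted p = 0.0783). The normal samples themselves differed. The mean log2 level of the list was 8.89, 8.37 and 8.72 in normal replicates 1 to 3 and 8.42, 8.36 and 8.23 in the cold storage replicates (exact permutation p = 0.2, 2-sided, where 0.1 is the smallest possible). In normal replicate 2, 24 of the 37 genes were no higher than in the highest cold storage sample. The number that fell was 25 without that sample, 9 without normal replicate 1 or 3, 8 without cold storage replicate 3, and 3 when only the 6 endothelial samples were fitted or counts were quantile normalised. The main fit shares 1 estimate of spread per gene among the 4 groups. The SD of the list level was 0.269 and 0.101 in endothelial normal and cold storage samples, but 0.022 and 0.018 in the epithelial ones. The 15 calls thus rest in part on the smaller epithelial spread. With only the 6 endothelial samples all calls numbered 87, against 93. HLA class I genes, which present peptides to cytotoxic T cells, formed the second list called. Of its 14 tested members 5 fell, 0 rose and 9 did not pass (5 fell when adjusted over the list alone). Their median was -0.18 (camera adjusted p = 0.0369, and adjusted p = 0.774 with an estimated correlation). B2M, the light chain of class I molecules, fell from 53177 ± 2775 to 43981 ± 1986 and HLA-B from 5566 ± 326.1 to 4630 ± 374.5 normalised counts (SD, n = 3 per group). B2M showed no difference after quantile normalisation, where both groups were set to one value. HLA-B did not pass after quantile normalisation (adjusted p = 0.178), with only the 6 endothelial samples (0.0612) or without cold storage replicate 3 (0.0705). In these 2 settings with every sample kept 1 gene of the list fell, and the list did not pass without normal replicate 1 (camera adjusted p = 0.289) or cold storage replicate 3 (0.189), or after thinning of the endothelial samples to the lowest total (0.0544). The interferon and class I lists shared 6 tested genes.

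Apoptosis and p53 targets were the third list called in the endothelium. It had 4 of 15 genes down, 0 up and 11 not passed (5 down when adjusted over the list alone), with a median of -0.09 (camera adjusted p = 0.0369, and adjusted p = 0.714 with an estimated correlation). The 4 were BCL2L11, CDKN1A, a cell cycle inhibitor induced by p53, FAS, a death receptor, and TNFSF10, a death ligand (the last chosen after its values were seen). CDKN1A fell from 6622 ± 144.3 to 4776 ± 174.9 and FAS from 551.8 ± 43.2 to 384.4 ± 19.7 normalised counts (SD, n = 3 per group). The list did not pass without normal replicate 2 (camera adjusted p = 0.0867), cold storage replicate 1 (0.0693) or cold storage replicate 3 (0.0824), or with the endothelial samples thinned to the lowest total (0.0733). Among the early response genes BTG2, an anti-proliferative p53 target, fell from 793.5 ± 48.0 to 493.9 ± 21.5 (adjusted p = 3.2e-05), and was the only one of 11 called. MYC had 645.6 ± 72.0 and 746.7 ± 9.6 and did not pass.

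No other list was called in the endothelium by camera, though single members changed. Some members that did not pass lay at or below the range of the viral targets. IL1A, CXCL10 and CD14, for instance, had 11.1, 5.8 and 2.2 normalised counts in endothelial normal samples (chosen after their values were seen). For such genes not passing says little. CD59, which blocks the membrane attack complex, rose from 24280 ± 611.9 to 27725 ± 1434 normalised counts (SD, n = 3 per group). In the complement list 1 of 13 genes rose, 3 fell and 9 did not pass. THBD, the anticoagulant receptor thrombomodulin, rose from 832.8 ± 20.9 to 1146 ± 66.7, and PLAU, the urokinase gene, fell from 1220 ± 59.7 to 928.6 ± 87.7. In the coagulation list 2 of 8 genes rose, 2 fell and 4 did not pass. Of 17 adhesion and activation genes 2 rose (CD44 and THBD), 2 fell and 13 did not pass. Of 24 matrix and TGF-beta genes 4 fell and 20 did not pass, among them ACTA2, the smooth muscle actin gene, which fell from 321.9 ± 40.2 to 210.0 ± 18.6, and BMP4, which fell from 398.6 ± 25.9 to 282.1 ± 5.2. The mitochondrial superoxide dismutase gene SOD2 fell (log2 -0.41 ± 0.08, SE) and the metallothionein gene MT1A rose (0.46 ± 0.09), with 1 of 5 oxidative stress genes up and 2 down. HK2 rose (0.42 ± 0.11) and HIF1A fell (-0.22 ± 0.07), with the other 4 of 6 hypoxia and glycolysis genes not passed. In the NF-kB list 1 of 29 rose (TNFAIP3, an inhibitor of NF-kB signalling, 0.43 ± 0.11), 2 fell, among them CSF1 (-0.59 ± 0.13), and 26 did not pass. In the cytokine list 4 of 29 fell, among them CCL5 (-0.51 ± 0.12), and 25 did not pass. Of 6 mTOR and PI3K genes IRS1 rose and 5 did not pass. None of 12 HLA class II or 23 innate sensing genes was called by the main edgeR fit, DESeq2 or limma with a pseudocount of 10 or 1, and 1 and 3 had an unadjusted p under 0.05. On unscaled counts 4 and 13 were called. With values under 20 set to 20, 3 innate sensing genes were called, and 1 with array weights or the replicate block. HLA-DRB1, CTSS, CASP1 and TLR3 had log2 differences of 0.95 ± 0.50, -0.39 ± 0.18, -0.32 ± 0.11 and -0.36 ± 0.14 (SE, n = 3 per group). HLA-DRB1 averaged 6.6 ± 0.7 and 12.7 ± 5.6 normalised counts (SD) in normal and cold storage samples, within the range of the viral targets. Its difference ran from log2 0 to 4.37 over the other settings on scaled counts and is not read as a change. After quantile normalisation CSF1, CCL5, TNFAIP3, HIF1A and CD59 did not pass (adjusted p = 0.073, 0.0836, 0.0739, 0.232 and 1), and with only the 6 endothelial samples CCL5 did not (0.0612). TNFAIP3 also did not pass without normal replicate 3 or cold storage replicates 1 or 3 (adjusted p up to 0.0842), and HK2 not without normal replicate 1 (0.0696). HIF1A did not pass without any 1 cold storage replicate (up to 0.0916), and CD59 without normal replicates 1 or 3 or cold storage replicate 3 (up to 0.145). On unscaled counts, where the median of all genes lay at log2 -0.46, HK2 and CD59 were at -0.01 and -0.23, and TNFAIP3, MT1A and THBD did not pass (up to 0.968).

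Among the markers of other cells in the endothelial channel, ACTA2 and RGS5, 2 of 3 mesenchymal markers, fell, while of 14 epithelial markers CAV1 rose, which is also an endothelial marker, and 13 did not pass (RGS5 and CAV1 chosen after their values were seen). Of 23 endothelial markers 2 rose, 4 fell and 17 did not pass. By the main edgeR fit, DESeq2 or limma with a pseudocount of 10 or 1, 0 of 7 leukocyte markers was called (1 at an unadjusted p under 0.05). On unscaled counts 2 were called, and 1 after subtraction of the viral targets.

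The third comparison asked the same of the epithelium. CXCL10, an interferon-induced T cell chemokine, fell from 82.5 ± 7.9 to 40.0 ± 2.6 normalised counts, and MMP9, a gelatinase, from 85.8 ± 24.3 to 39.8 ± 11.9 (SD, n = 3 per group). GBP4 fell from 66.0 ± 7.8 to 39.0 ± 5.7, and ATF3, a stress-induced transcription factor, from 362.9 ± 12.7 to 220.6 ± 13.5. The exonuclease gene ISG20 fell from 148.0 ± 16.1 to 94.7 ± 7.5 and IL23A from 113.8 ± 12.4 to 72.8 ± 10.6. EZH2, a histone methyltransferase, rose from 182.9 ± 7.6 to 251.4 ± 9.5, DNMT1, the maintenance DNA methyltransferase, from 455.4 ± 20.8 to 615.7 ± 72.4, and MCM6, a subunit of the replicative helicase, from 730.9 ± 41.4 to 928.6 ± 44.5. The decoy receptor gene IL1R2, MYBL1 and VCAN rose by log2 0.47 ± 0.13, 0.45 ± 0.12 and 0.44 ± 0.13 (SE).

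In the epithelial channel 39 genes changed, 13 up and 26 down, 2 of them over 2-fold. The groups did not overlap in 165 of the 580 tested genes (28.4%, where chance gives 10%), and 38 of these were called. Housekeeping scaling gave 8 up and 56 down, median-of-ratios scaling 9 up and 49 down, and 77 genes were called without cold storage replicate 1, 10 up and 67 down. IL1R2 and VCAN each lost their call under 11 of 15 other settings (adjusted p up to 0.474 in both), MYBL1 under 7 (0.281), MMP9 under 3 (0.354), IL23A and GBP4 under 2 (0.179 and 0.0552) and CXCL10 under 1 (0.126). EZH2, DNMT1 and MCM6 did not pass on unscaled counts (up to 0.525). Calls were also lost for IL1R2 without normal replicates 2 or 3 or cold storage replicates 2 or 3 (adjusted p up to 0.325), and for VCAN and MMP9 without normal replicates 1 or 2 or cold storage replicates 2 or 3 (up to 0.286 and 0.0985). MYBL1 lost its call without any epithelial sample other than cold storage replicate 1 (up to 0.18), and GBP4 without normal replicate 1 or cold storage replicates 2 or 3 (up to 0.0883).

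Cytokines and chemokines were the list with the lowest p in the epithelium. Of its 29 tested members 6 fell, 0 rose and 23 did not pass (7 fell when adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.00132, and adjusted p = 0.188 with an estimated correlation). IL1A and IL1B, which encode the inflammatory cytokines interleukin-1 alpha and beta, fell from 906 ± 40.9 to 641.2 ± 77.2 and from 189.4 ± 19.4 to 125.5 ± 5.4 normalised counts (SD, n = 3 per group). The number that fell was 1 after quantile normalisation, 2 and 0 by limma with pseudocounts of 10 and 1, and 5 to 8 under the other settings. IL1B lost its call under 4 of 15 settings (adjusted p up to 0.26) and IL1A under 2 (0.157), quantile normalisation and limma with a pseudocount of 1 in both cases. CCL20, CSF2 and CXCL11 fell as well, by log2 0.58, 0.58 and 0.37 (chosen after their values were seen). The NF-kB list, which shared 11 tested genes with the cytokine list, had 4 of 29 down, all 4 of them cytokines, 0 up and 25 not passed. Adjusted over the list alone, 8 fell and 1 rose, and the median was -0.17 (camera adjusted p = 0.00615, and adjusted p = 0.548 with an estimated correlation). In the NF-kB list 0 fell after quantile normalisation or by limma with a pseudocount of 1, 1 with a pseudocount of 10, and 8 with housekeeping or median-of-ratios scaling, either other filter or array weights. The list did not pass without cold storage replicate 2 (camera adjusted p = 0.0735).

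Interferon-stimulated genes and both HLA lists were also called downward in the epithelium. Of 37 interferon-stimulated genes 5 fell (also 5 over the list alone), 0 rose and 32 did not pass, with a median of -0.09 (camera adjusted p = 0.00615, and adjusted p = 0.637 with an estimated correlation). CXCL10, GBP4 and ISG20 were among the 5, and 2 to 7 fell under the other settings. The mean log2 level of the list was 7.98 ± 0.022 in normal and 7.82 ± 0.018 in cold storage samples (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Of 14 HLA class I genes 1 fell, HLA-B, from 2233 ± 56.2 to 1798 ± 109.7 normalised counts (also 1 over the list alone). The number was 4 with housekeeping scaling, median-of-ratios scaling, DESeq2 or a filter at 50 counts, 3 without a filter or with only the 6 epithelial samples, and 0 on unscaled counts. TAPBP, at log2 -0.20 ± 0.07 (SE), did not pass, and the median of the list was -0.19 (camera adjusted p = 0.00741, and adjusted p = 0.548 with an estimated correlation). None of 12 HLA class II genes was called over all genes by edgeR with TMM scaling and the filter at 20 counts, by DESeq2 or by limma with a pseudocount of 10 or 1 (7 had an unadjusted p under 0.05), and 4 fell when adjusted over the list alone. Under other settings 4 fell with housekeeping or median-of-ratios scaling or with array weights (limma), 3 without a filter, and 1 with a filter at 50 counts or with only the 6 epithelial samples. Their median was -0.31 (camera adjusted p = 0.00741, and adjusted p = 0.548 with an estimated correlation). HLA-DRB1 and CTSS were at -0.42 ± 0.13 and -0.37 ± 0.12 (SE). Without cold storage replicate 3 the interferon list (camera adjusted p = 0.0561) and both HLA lists (0.0741 each) did not pass, and the class II list also not without normal replicate 3 (0.217) or cold storage replicate 2 (0.15).

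**Figure D2:**
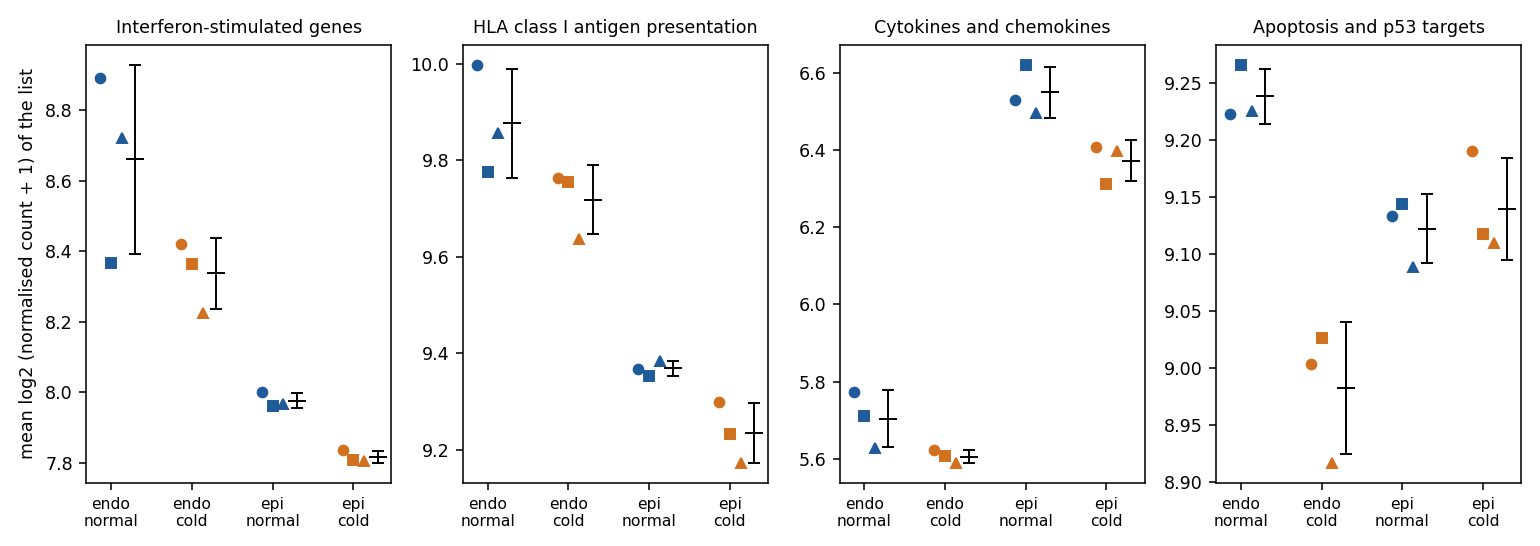
Mean log2 (normalised count + 1) over the tested members of 4 gene lists in each sample (vertical axes differ between panels and do not start at 0), for the normal and cold storage groups of the endothelial (endo) and epithelial (epi) channels. Circles, squares and triangles are replicates 1 to 3, and black bars are the group mean and SD (n = 3); for the interferon-stimulated genes, endothelial normal replicate 2, at 8.37, lies among the cold storage samples at 8.42, 8.36 and 8.23.

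The remaining lists were not called in the epithelium by camera. CDKN1A fell from 1236 ± 125.5 to 861.9 ± 66.1 normalised counts (SD, n = 3 per group) and was the only one of 15 apoptosis and p53 genes called, while BIRC3, at log2 0.21 ± 0.07 (SE), did not pass. ATF3 was the only one of 11 early response genes called, and FOS, at 0.24 ± 0.08, did not pass. FN1, the fibronectin gene, fell from 385.7 ± 34.5 to 277.0 ± 35.4, so that with MMP9 2 of 24 matrix genes fell, 2 rose and 20 did not pass. Of 17 adhesion genes NOS3, endothelial nitric oxide synthase, fell from 203.0 ± 6.1 to 132.4 ± 16.8, PECAM1, a junctional adhesion molecule of endothelium, rose from 361.2 ± 9.9 to 437.4 ± 36.6, and 15 did not pass. PECAM1 lost its call without any single normal replicate or without cold storage replicate 1 (adjusted p up to 0.128). SOD2 fell from 1524 ± 70.3 to 1283 ± 113.4, as 1 of 5 oxidative stress genes (not passed under 4 of 15 settings, adjusted p up to 0.467), and MT1A, at log2 0.21 ± 0.07 (SE), did not pass. None of 6 hypoxia, 8 coagulation, 13 complement, 6 mTOR or 23 innate sensing genes was called by the main edgeR fit or limma with a pseudocount of 10 or 1. DESeq2, array weights and edgeR with housekeeping or median-of-ratios scaling called 1 hypoxia, 2 coagulation and 1 mTOR gene. So did edgeR without a filter, with a filter at 50 counts or with the replicate block. With only the 6 epithelial samples 1 gene of each of these 3 lists was called. In the innate sensing list 1 gene was called with array weights, only the 6 epithelial samples, the replicate block or subtraction of the viral targets. Of the hypoxia, coagulation, complement, mTOR and innate sensing genes 1, 2, 1, 1 and 2 had an unadjusted p under 0.05 with edgeR. The smallest p-values of the hypoxia, coagulation, mTOR and innate sensing lists belonged to VEGFA (-0.22 ± 0.08), THBD (-0.24 ± 0.07), RPS6 (-0.17 ± 0.06) and HMGB1 (0.25 ± 0.08). No epithelial, mesenchymal or leukocyte marker was called by the main edgeR fit or limma with a pseudocount of 10 or 1 in this channel, of 14, 3 and 7 tested. DESeq2 and edgeR with housekeeping or median-of-ratios scaling or without a filter called 1 epithelial marker. Array weights, only the 6 epithelial samples and the replicate block called 2. Of the 3 kinds of marker 3, 0 and 0 had an unadjusted p under 0.05. NOS3 and PECAM1 were the 2 of 23 endothelial markers called.

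In the lists too small to test, XBP1, a regulator of the unfolded protein response, rose in the endothelium and fell in the epithelium, and HSP90AA1 did not pass in either (both chosen after their values were seen). MCM6 did not pass in the endothelium (chosen after its values were seen), and CTSL (likewise), CTSS and LAMP1 passed in neither channel with edgeR, DESeq2 or limma with a pseudocount of 10 or 1 (1 of the 3 had an unadjusted p under 0.05 in each). On unscaled counts all 3 were called in the endothelium, and 1 was called in the epithelium with housekeeping or median-of-ratios scaling or array weights.

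The fourth comparison asked whether cold storage acted differently on the 2 channels, by testing the difference of the effects. The difference passed for 27 of 580 genes, 15 with the endothelial effect above the epithelial one and 12 below it. Above it were TNFAIP3, by log2 0.78 ± 0.16, IL1RL1, the interleukin-33 receptor, by 0.76 ± 0.16, and THBD by 0.70 ± 0.10 (SE, n = 3 per group). So were NOS3 by 0.69 ± 0.13, id2, an inhibitor of DNA binding, by 0.64 ± 0.12 and ATF3 by 0.62 ± 0.12. Below it were BCL2L11, by -1.24 ± 0.24, BMP4 by -0.84 ± 0.14, GBP2 by -0.71 ± 0.19, BTG2 by -0.69 ± 0.15, FAS by -0.65 ± 0.12 and PECAM1 by -0.63 ± 0.09. For BCL2L11, near background in endothelial cold storage, the value ran from -1.84 to -1.02 over the other settings on scaled counts. THBD rose in the endothelium, where it gained log2 0.46 ± 0.07, and had -0.24 ± 0.07 without passing in the epithelium. BMP4 and PECAM1 moved in opposite directions. BMP4 fell by 0.50 in the endothelium and rose by 0.34 in the epithelium. PECAM1 fell from 7912 ± 213.5 to 6183 ± 130.9 normalised counts in the endothelium (SD, n = 3 per group) and rose in the epithelium. No gene list was called for the difference by camera, the lowest adjusted p being 0.0667 for apoptosis and p53 targets.

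Housekeeping scaling gave 31 above and 8 below, and median-of-ratios scaling 28 above and 9 below. The count was 74 without endothelial normal replicate 2, 53 without epithelial cold storage replicate 1, and 41 without epithelial normal replicate 3 or without epithelial cold storage replicate 2. BTG2 did not pass without epithelial cold storage replicate 2 (adjusted p = 0.0702). With TMM scaling GBP2 passed only with every sample or without endothelial normal replicates 2 or 3, endothelial cold storage replicate 2 or epithelial normal replicate 3 (adjusted p up to 0.107 otherwise). With every sample it lost its call under 6 of 14 other settings (up to 0.178), housekeeping scaling, quantile normalisation and DESeq2 among them. TNFAIP3, IL1RL1, THBD, NOS3, id2 and ATF3 did not pass on unscaled counts (up to 0.397).

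The same 5 genes fell in both channels, CDKN1A, CXCR4, GBP4, HLA-B and SOD2, where 2.73 would be shared by chance (Fisher's exact test, 1-sided p = 0.126), and 0 rose in both against 0.717 by chance. BMP4, PECAM1 and XBP1 changed in opposite directions, 3 genes against 2.80 by chance. Across the 580 genes, which are not independent replicates, the fold changes of the channels had a Pearson r of 0.123 and a Spearman rho of 0.129. Genes at background in 1 channel are among the 580 and enter these values and the numbers given by chance.

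**Figure D3:**
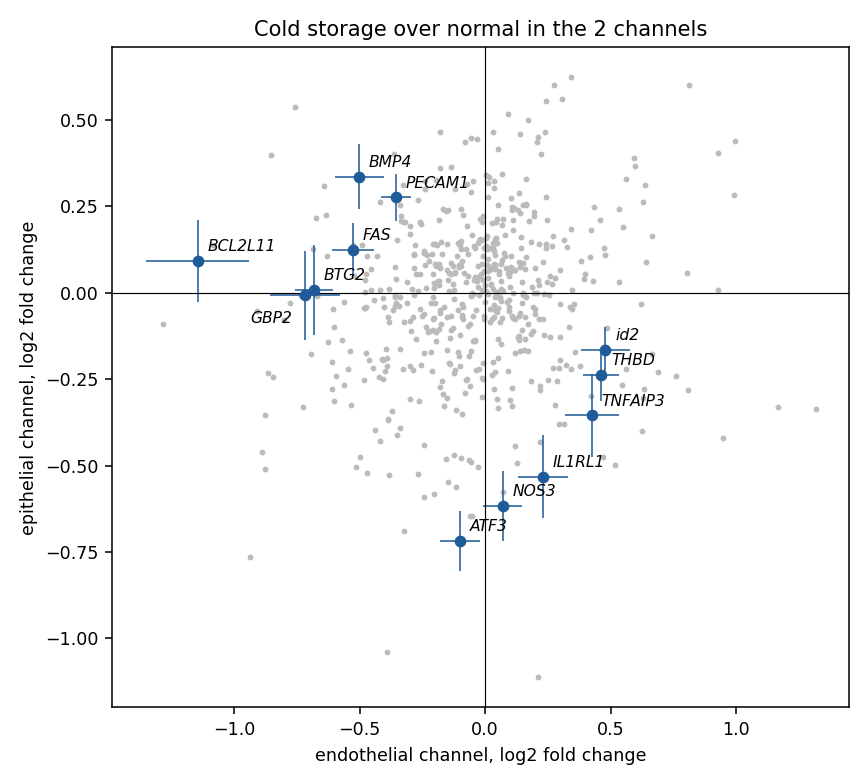
Log2 fold change of cold storage over normal in the endothelial (horizontal) and epithelial (vertical) channel for the 580 tested genes (grey points). The 12 named genes of the difference between channels are shown in blue with SEs from fits with 3 samples per group; BMP4 and PECAM1 lie in the upper left, and THBD, id2 and TNFAIP3 in the lower right.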

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

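The effect of cold storage differed between the endothelial and epithelial channels by the test of the difference itself for 27 genes. Among the 100 splits of the samples within each channel that were drawn, 1 gave as many genes, the real one. The highest of the others gave 11, so a count of 27 was rare among the splits drawn. Splits that mix cold storage with normal samples carry the cold storage effects in their spread, which can lower their counts. Such splits also cannot exclude differences between cultures or chips other than cold storage. The endothelial effect was above the epithelial one for TNFAIP3 by log2 0.78, IL1RL1 by 0.76, THBD by 0.70, NOS3 by 0.69, id2 by 0.64 and ATF3 by 0.62. It was below for BCL2L11 by -1.24, BMP4 by -0.84, GBP2 by -0.71, BTG2 by -0.69, FAS by -0.65 and PECAM1 by -0.63. Of these, THBD and TNFAIP3 rose in the endothelium without passing in the epithelium. NOS3, IL1RL1 and ATF3 fell in the epithelium without passing in the endothelium, and BCL2L11, GBP2, BTG2 and FAS fell in the endothelium without passing in the epithelium. GBP2 and BTG2 are the least certain: GBP2 lost its call without 8 of the 12 samples in turn (adjusted p up to 0.107), and BTG2 without epithelial cold storage replicate 2 (0.0702).

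PECAM1, an endothelial gene, fell in the endothelial channel and rose in the epithelial channel. The test of its carry-over was chosen only after the result was seen. Endothelial RNA or cells carried into the epithelial channel would bring all abundant endothelial transcripts, so the lowest share among them bounds its extent. In normal chips the epithelial level was 4.57% of the endothelial one for PECAM1 against 0.173% for ECSCR, 0.460% for TM4SF18, 0.778% for TEK and 0.977% for CDH5. Other genes higher in the endothelium lay near or above PECAM1, with NOS3 at 16.5%, ICAM2 at 9.65%, IL1RL1 at 6.40%, BMP6 at 3.83% and FN1 at 3.60%, so the share was not uniform (genes chosen after their values were seen). The ratio of PECAM1 to the lowest of these was 26.4, which argues against carry-over as the source of most of the epithelial PECAM1 counts. The rise itself, from 361.2 to 437.4 normalised counts, is small and lost its call without any single normal replicate or without cold storage replicate 1 (adjusted p up to 0.128). A response of the epithelial cells to cold storage stays open and was not tested further.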

How the results depend on the processing

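Thinning, subtraction of the viral targets and limma with a pseudocount of 1 were chosen only after the data were seen. For 107 results on named genes, 2325 of 2331 recomputed values kept their direction or were 0, 2057 of these also their side of the threshold, while 173 lost and 95 gained a call. The 2 called values that reversed were HK2 at log2 -0.0145 and CD59 at -0.23 in the endothelium on unscaled counts, where lower totals move the median of all genes to -0.46. The number of differences between channels, 472, stayed within 1.5 times under every setting, though single folds and calls moved more, as given above. Endothelial calls numbered 296 (0 up) without scaling, 61 after quantile normalisation and 55 to 113 with 1 sample left out. Epithelial calls numbered 64 with housekeeping scaling, 16 without scaling, 25 and 20 by limma with pseudocounts of 10 and 1, and 61 with a filter at 50 counts. They numbered 74 with array weights, 66 with only the 6 epithelial samples and 31 to 77 with 1 sample left out. The difference between channels gave 89 genes without scaling, 42 with a filter at 50 counts, 74 with values under 20 set to 20, 72 with array weights, 42 after subtraction of the viral targets and 20 to 74 with 1 sample left out. Except where a cause is named, the cause was not tested.

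With an estimated inter-gene correlation no list was called. In the endothelium the adjusted p was 0.774 for interferon-stimulated and HLA class I genes and 0.714 for apoptosis. In the epithelium it was 0.188 for cytokines, 0.548 for NF-kB and both HLA lists and 0.637 for interferon-stimulated genes. By fry, which tests a list by itself, it was 0.0604 and 0.0578 for the endothelial interferon and HLA class I lists, and 0.0824 for NF-kB and both HLA lists and 0.241 for the interferon list in the epithelium. Fry passed endothelial apoptosis (0.00193), epithelial cytokines (0.00722) and, not called by camera, endothelial complement (0.00439) and apoptosis in the difference (0.0102). The replicate block gave 0.235 for endothelial HLA class I and apoptosis, and thinning 0.0544 and 0.0733. With 1 sample left out the adjusted p of camera ran from 0.00427 to 0.289 and 0.0236 to 0.0867 for those lists. In the epithelium it ran from 0.000122 to 0.0735 for NF-kB, 0.0105 to 0.0561 for interferon-stimulated genes, 0.00495 to 0.0741 for HLA class I and 0.000122 to 0.217 for HLA class II. Same-numbered samples correlated at -0.211 to 0.114 after removal of group means, not over 0.1 in every pair, and were read as sharing only a number. Between the epithelial groups (0.0689 to 0.114) and between the normal groups (0.0558 to 0.104) 3 of 3 samples correlated best with their own number, and 1 of 3 in each of the other 2 comparisons, a hint from the data and not the design. As a block the numbers gave 76 endothelial, 85 epithelial, 36 difference and 455 channel calls, and IRS1, IL21R, BST2, ABCA1, CSF1, B2M, HK2 and HIF1A were not called in the endothelium (adjusted p 0.053 to 0.094). With it 5 HLA class I and 5 HLA class II genes fell in the epithelium, against 1 and 0 without. Test and mean differ in sign for the endothelial coagulation and adhesion lists, and test and median for the endothelial HLA class II list, none of them called. Targets under about 25 normalised counts lie within the viral background.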

Other observations

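The panel with its custom probes held 28 genes of BMP, activin and SMAD signalling, a group put together after the values were seen, of which 25 were tested. In the endothelium the BMP target genes id1 and id2 rose, from 3877 ± 670.6 to 5238 ± 493.8 and from 124.7 ± 6.5 to 173.8 ± 5.5 normalised counts (SD, n = 3 per group), while the ligand gene BMP4 fell. In the epithelium BMP4 and SMAD5 rose, SMAD5 from 394.3 ± 25.4 to 497.4 ± 21.2, and BMP6 fell from 123.9 ± 2.6 to 83.9 ± 11.8. As a group these genes were not called (limma's camera, adjusted p = 0.809 in the endothelium, 0.153 in the epithelium and 0.449 for the difference). SMAD4, the common partner of the receptor SMADs, had 320.7 ± 15.3 normalised counts in endothelial normal samples but 8.8 ± 0.4 in epithelial normal and 12.1 ± 3.7 in epithelial cold storage samples, within the range of the viral targets. These epithelial counts are read as background. The same probe also gave 312.6 ± 12.2 in endothelial cold storage samples, and the endothelial counts argue against a probe that fails in general. Why the epithelial counts were at background was not tested. The junction genes cdh1, CDH5, CTNNB1 and tjp1 were not called with cold storage in either channel by edgeR (chosen after their values were seen). For cdh1 in the endothelium (27.9 and 29.3 normalised counts in normal and cold storage) and CDH5 in the epithelium (21.0 and 26.3) this says little. Those levels lay in or near the range of the viral targets. PECAM1, also a junctional gene, was called in both channels. CTNNB1 was at log2 0.03 ± 0.06 and 0.01 ± 0.06 (SE) in the endothelium and epithelium.

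GDF15, a stress-induced cytokine gene and p53 target outside the lists, fell in the endothelium from 1348 ± 59.4 to 816 ± 42.7 normalised counts (SD, n = 3 per group, edgeR adjusted p = 8.31e-05), beside the falls of CDKN1A, FAS and BTG2 (chosen after its values were seen). SFTPB and SFTPC, transcripts of distal lung epithelium, were low in the epithelial normal samples (both chosen after their values were seen). SFTPB, at 31.0 ± 3.26 normalised counts, lay just above the range of the viral targets and SFTPC, at 14.5 ± 4.68, within it, in contrast to KRT19 at 14104 ± 253.5.

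Among the tests of the patterns that follow, the one over splits of the interferon list was chosen only after the result was seen. Thinning was added after the data were seen. Interferon-stimulated genes had a median of log2 -0.39 in the endothelium, where 15 of 37 fell and 22 did not pass (camera adjusted p = 8.29e-06, 0.774 with an estimated correlation and 0.0604 by fry). With all 6 endothelial samples thinned to the lowest total the median was -0.33. Thinning removes counts of all genes in a sample at 1 rate, and scaling follows, so it could hardly move the median. It therefore cannot decide whether less RNA or a larger share of background in the cold storage samples contributed. A scale factor moves all genes of a sample alike, so among the scalings only quantile normalisation could bring the list nearer to the other genes. With it the gap between the list median and that of all genes was -0.27, against -0.36 before, which argues against scaling as the whole explanation, though 3 genes were called in place of 15. That setting also changed the test to limma with a pseudocount of 1. With TMM scaling the same test gave a gap of -0.33 and 11 calls. The treatment of low counts also moved the gap, to -0.27 by limma with a pseudocount of 10 and -0.29 after subtraction of the viral targets. Whether 1 library carries part of the fall stays open. The highest median with 1 sample left out was -0.24, without normal replicate 1, where the median of all genes was -0.059 and the gap -0.18. A bound on the list median alone, set at -0.2 beforehand, did not allow for that shift. A difference between chips in one program shared by these genes cannot be told apart from cold storage with 10 splits of 6 samples. Only 1 split, the real one, had a list median as far from 0 (0.388 against 0.325 for the highest other). For the mean level per sample, 2 of the 10 splits were as large. The normal samples alone spanned 8.37 to 8.89 in that mean, so interferon tone may vary between chips as much as with cold storage, and more chips would be needed to separate them.

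Endothelial cold storage samples had 74.0% of the mean total of endothelial normal samples. A few abundant genes do not account for this, since the ratio was 0.723 without the 10 most abundant genes, which held 36.2% of the counts. The median ratio over the tested genes was 0.729 and 92.6% of them had lower raw means, as a general fall such as less RNA or less efficient hybridisation would give. Loss of cells or of RNA under cold storage and a smaller RNA input stay open, since the RNA input is not given in the sources used here.

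Splits of the 6 samples behind each of the other counts number 10, too few for a share under 0.05. The real splits gave 93 genes in the endothelium, 39 in the epithelium and 472 between channels, the real one being the 1 split with as many genes in each case, and the highest other splits gave 5, 1 and 0. The other splits mix the groups compared, so real differences enter their spread and lower their counts, most of all between channels. Their counts are therefore no measure of what chance gives.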
